A study of Mus musculus with 8 samples.

How the data were processed

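PRO-seq libraries of mouse FUCCI2 induced pluripotent stem cells were analysed in 4 groups: mitotic cells after nocodazole, cells released for 1 h and 3 h, and asynchronous cells. The labels list 2 libraries per group. The deposited table holds 1 column per group, so the 2 libraries had already been combined. How they were combined is not given in the sources used here.

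The values are a normalized PRO-seq signal per gene made by the authors, per the file headers. Reads were processed with cutadapt, Bowtie2, Picard and SAMtools on GRCm38/mm10, per the submitters' processing notes, which give no versions or order. How reads were assigned to genes, whether strand was used, and how libraries were scaled are not given in the sources used here. Other facts come from the values. They are not whole numbers, and the highest value of each gene over the 4 columns is at least 1.02. The columns were not scaled to 1 total, since they sum to 16863 in mitosis, 361203 in early G1, 326086 in late G1 and 309144 in asynchronous cells. Of 9 pairs of transcripts that share a TSS, 3 kept a constant ratio within 1% in all columns. The ratio was exactly 1 for Gm42878 and Adam1a. For Pagr1a and Gm42742 it was 0.995 in late G1 and 0.986 in the other columns. Only the ratio of Ugt1a7c and Ugt1a6b stayed fixed away from 1 (0.989), as values divided by a length would. The scaling sets the comparison of mitosis with the other groups, and no spike-in value was used here. The table also deposited by the authors names a temporal class for each gene, a text label of another kind of unit, and how the classes were made is not given in the sources used here. No counts or depths were used, so the depth is unknown and no counting interval or floor is given. Intervals in the tests of explanations come from resampling genes and do not cover replicates.

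The columns named early G1 and late G1 were matched to the 1 h and 3 h releases by meaning. Coordinates are those of the table, on GRCm38. Gene symbols were matched to the RefSeq annotation of GRCm38.p6: 14401 directly, 206 through a synonym and 254 not at all. A span within reach of the table's TSS (1000 bp) was found for 14381 genes, with a median of 21488 bp.

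The tests fixed before the data were examined assumed 8 library columns and were limma on log2 values, with camera and fry for gene lists. With 1 column per group these could not be run, so no test across genes, p-value or SD is given. They were replaced by descriptions: the log2 ratio of (signal + 0.1), a minimum mean signal of 0.5, and a count of genes at least 2-fold higher or lower. The pseudocount makes such a fold understate the change of low genes. Percentages of the asynchronous signal kept in mitosis carry no pseudocount. The threshold share of the asynchronous signal used for timing in early and late G1 was applied to the fold, so it carries the pseudocount. The filter removed 47 genes and left 14814. A value of exactly 0 was treated as listed at 0 and not as a measured level, because 431 genes had one somewhere, 60 of them above the median level. Such genes were left out of folds that use that column. The 4 main comparisons were made (mitotic against asynchronous, early G1 against mitotic, late G1 against early G1, late G1 against asynchronous), with early G1 against asynchronous and late G1 against mitotic as support. Because scaling moves the median gene by over 0.1 on the log2 scale, changes of gene lists are given relative to the median gene.

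Before the data were examined, 34 gene lists were fixed, of which 30 had at least 5 members in the table. Each list's median was placed among 10000 random lists of the same size drawn from 10 bins of mean signal, as a description of these columns. A list was said to stand apart at a percentile of 0.5 or less, or 99.5 or more. Across the 4 main comparisons 21 of 120 placements stood apart, against 1.2 expected for lists of unrelated genes. Genes of 1 list may vary together, some genes are on several lists, and the comparisons share columns. The value of 1.2 is therefore no bound for the lists used here. The step was tested on simulated data made from late G1 against asynchronous cells (14695 genes), with the log2 ratios shuffled over genes and list members drawn at random. Members therefore moved independently, and the simulation does not cover lists whose genes vary together. Lists of 15 genes shifted by 0, 0.5 and 1 on the log2 scale stood apart in 0.5%, 23% and 96.5% of 200 simulations, and lists of 30 genes in 0.5%, 70% and 100%.

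Named genes follow a rule fixed beforehand, with the fold in place of the test: for each main comparison the 6 largest and 6 smallest ratios among genes at or above the median level without a predicted or clone name, up to 4 members per list with the largest change, and 12 genes given always (Pou5f1, Sox2, Nanog, Klf4, Esrrb, Myc, Ccnb1, Ccnd1, Ccne1, Fos, Egr1 and Col1a1). The rule was not followed in full, since not all of these 12 are given in every comparison. Fos and Egr1 are given only for mitotic against asynchronous cells. Myc, Ccnb1, Ccnd1 and Ccne1 are given only for late G1 against asynchronous cells. A few genes are also given outside the comparison that selected them. Alternatives were pseudocounts of 0.5 and 0.02, no filter, a minimum mean of 2.5, equal medians and quantile normalization. Added after seeing the data were genes at 0 kept, spans of at least 2 kb, folds of 1.5 and 4, random lists matched on span, and list means. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.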

Results

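PRO-seq maps RNA polymerases that are engaged in transcription by letting them extend their nascent RNA with labelled nucleotides in isolated nuclei, so its signal over a gene reads ongoing transcription. It was applied to mouse induced pluripotent stem cells that carry the FUCCI2 cell-cycle reporter and were grown on irradiated feeder cells with LIF and inhibitors of MEK and GSK3. Cells were held in mitosis with the microtubule poison nocodazole (200 ng/ml for 6 h), collected by shake-off, and either taken at once or released into fresh medium for 1 h or 3 h. Untreated cycling cells served as the asynchronous group. The labels list 8 libraries, 2 for each of the 4 groups, while the deposited table gives 1 combined value per gene and group for 14861 genes. Its columns named early G1 and late G1 were taken as the 1 h and 3 h releases, a match by meaning that the labels do not spell out. There is therefore no replicate check on any difference given here, and each value is the authors' value. The depth of the libraries is unknown.

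**Figure D1:**
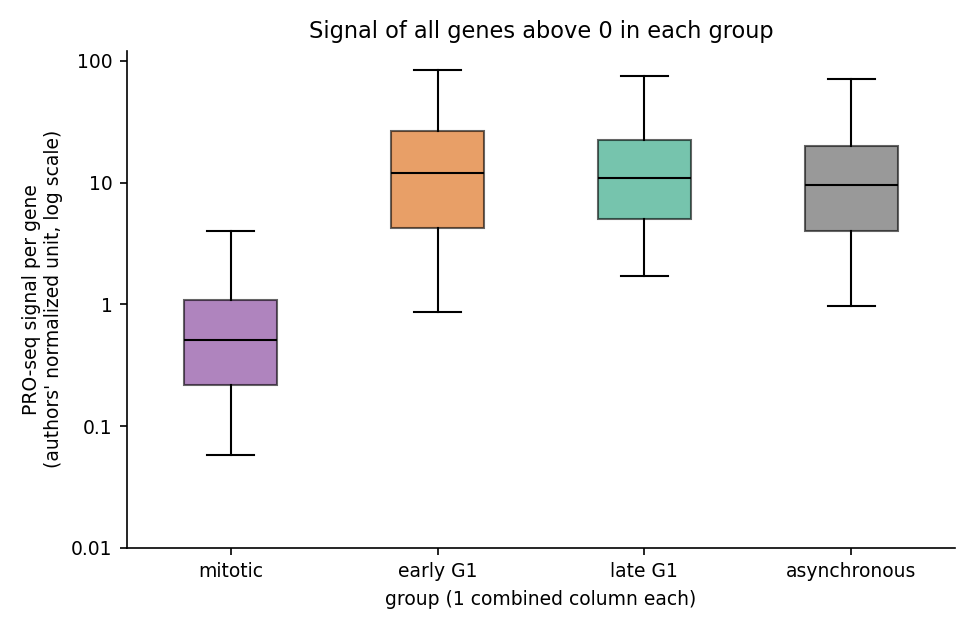
Boxes show the median and quartiles, and whiskers the 5th and 95th percentiles, of PRO-seq signal per gene (authors' normalized unit, log axis) for genes above 0 in each of the 4 groups. The mitotic group lies far below the other 3; over all genes, its median is 0.489, against 11.8 in early G1, 10.9 in late G1 and 9.43 in asynchronous cells.

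The first question was how much transcription remained in mitosis. Nearly every gene was lower in mitotic than in asynchronous cells: 14321 of 14444 genes were at least 2-fold lower, and 3 were at least 2-fold higher. The median gene kept 5.30% of its asynchronous signal, and the column total was 5.45% of the asynchronous total. The 3 higher genes, named after their values were seen, were Nmrk2 (1.05 in mitosis, 0.172 in asynchronous cells), Olfr543 (14.2 and 3.79) and Lrit1 (0.216 and 0.0507). The pluripotency transcription factors fell with the rest of the genome. Pou5f1, which encodes OCT4 (chromosome 17, TSS at 35506018 in GRCm38), had a signal of 3.90 in mitosis and 139 in asynchronous cells. Nanog had 6.14 and 136, Sox2 13.6 and 226, Klf4 10.7 and 147, and Esrrb 3.12 and 61.0. Across 26 naive pluripotency factors the median lay at percentile 5.55 of 10000 random lists of the same size and expression level, within the range of 99% of them.

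Some gene groups kept more mitotic signal than others. The 25 p53 targets, genes induced by the stress-responsive transcription factor p53, had a median log2 ratio 1.42 above that of the median gene, above all or nearly all random lists (percentile 100). Plk2, a kinase gene (chromosome 13, TSS at 110395048), had 34.3 in mitosis and 36.1 in asynchronous cells. Ccng1, which encodes cyclin G1, kept 33.0%, Rps27l 35.7% and Fas, a death receptor gene, 21.4%. The 28 immediate early genes, which respond to growth factors without new protein synthesis, lay 0.72 above the median gene (percentile 100); Fos kept 29.4% and Atf3 29.4%, and Egr1 kept 15.2%. The 15 G1 cyclins and CDK inhibitors lay 0.53 above (percentile 99.91, and 99.3 in the least favourable setting tried), with Cdkn1a, which encodes the CDK inhibitor p21, at 23.1 in mitosis and 117 in asynchronous cells.

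Ribosomal protein genes and glycolytic genes lost more than the median gene. The 79 ribosomal protein genes had a median log2 ratio of -0.94 relative to the median gene (percentile 0), and 33 of them lay at least 2-fold below it. Rps21 went from 252 in asynchronous cells to 3.07 in mitosis, and Rps4x from 298 to 3.96, while Rpl8 kept 28.2% and Rps27l, which is on the p53 list as well, 35.7%. The 20 glycolytic genes lay at -0.71 (percentile 0.04), with Gapdh at 12.4 and 405, Ldha at 1.60 and 73.3, and Gpi1 at 0.582 and 23.8. Tubulins (-0.52, percentile 2.435) and G2 and mitosis genes (-0.34, percentile 2.90) were low but within the range of 99% of random lists. The G2 and mitosis genes left that range in the most extreme setting tried (percentile 0.07), and the tubulins did not (2.19). The pseudocount of 0.1 weakens the fall of weak genes, so it makes part of the deficit of highly transcribed lists relative to the median gene. With a pseudocount of 0.02 the log2 ratio of the median gene moved from -3.89 to -4.14. The percentiles compare each list with random lists of like level.

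Among genes with a mean signal at or above the median, the highest mitotic to asynchronous ratios after Olfr543 belonged to Mab21l1, Rfpl4, Gstp3, Plk2 and Bex3. Mab21l1 (0.646 and 0.328) lies inside the gene Nbea, so its signal cannot be assigned to it with certainty. Gstp3, a glutathione transferase gene, had 17.9 in mitosis and 17.5 in asynchronous cells. The lowest ratios belonged to Saa3, an acute-phase gene (0.0543 and 41.6), Grrp1 (0.395 and 103), Gnat1 (0.527 and 104), Ssc4d (0.324 and 67.3), Arl11 (0.0353 and 21.1) and Trp53i11 (0.0765 and 26.0). The mitotic values are small, and the fold of the median gene depends on the pseudocount, from a log2 ratio of -3.23 at 0.5 to -4.14 at 0.02. Rescaling the columns to equal medians removes the general fall by construction and leaves 1690 genes higher and 908 lower.

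**Figure D2:**
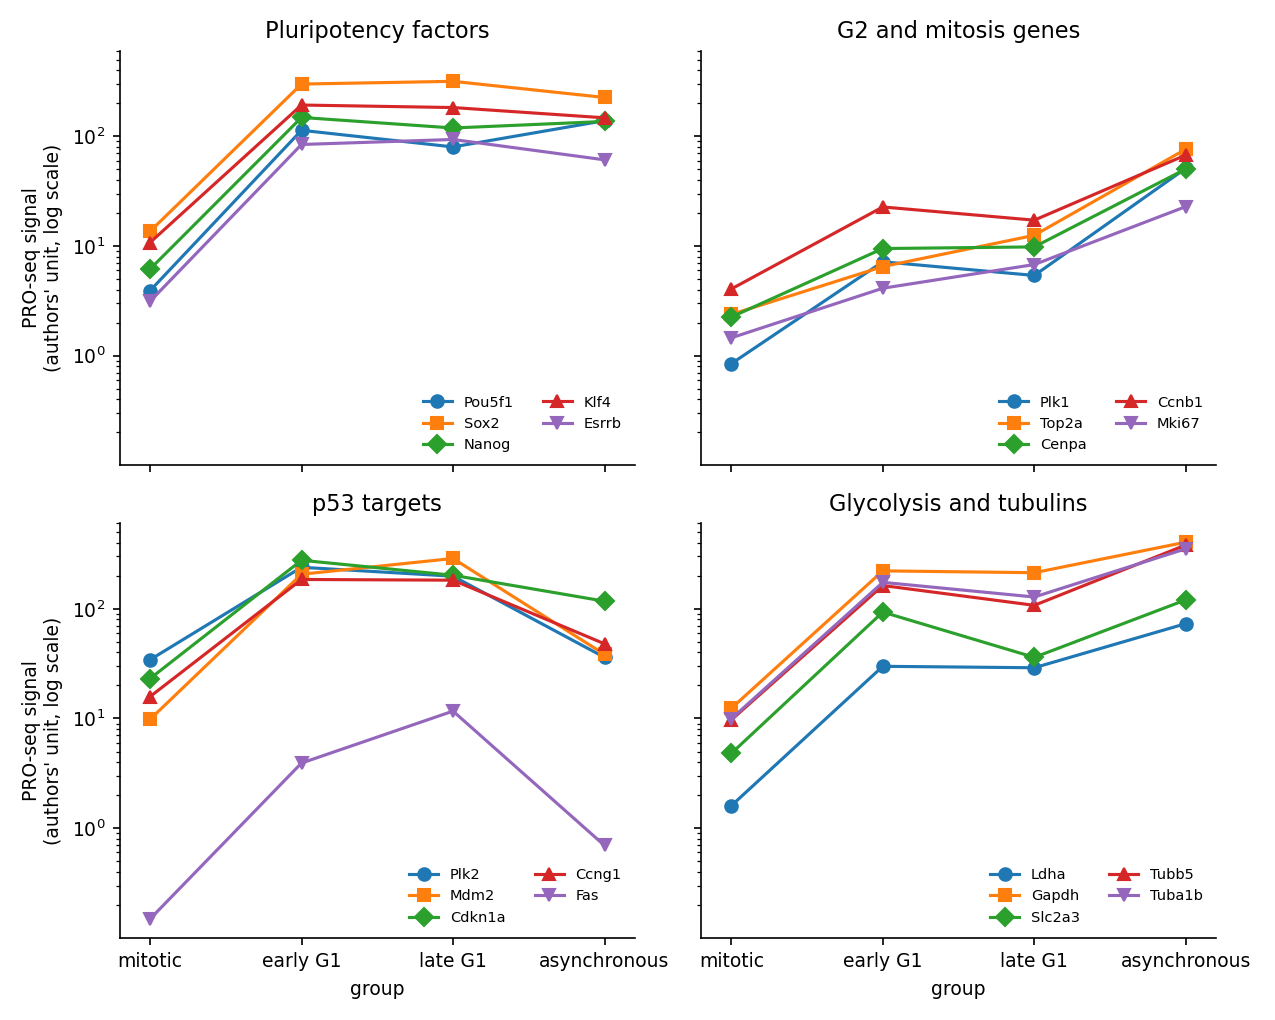
Lines join the PRO-seq signal (authors' unit, log axis) of 5 genes per panel across the mitotic, early G1, late G1 and asynchronous groups, with 1 value per point. Pou5f1 rises from 3.90 to 113 by early G1, Plk1 reaches 5.38 in late G1 against 51.1 in asynchronous cells, and Mdm2 reaches 288 in late G1 against 38.4.

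The second comparison followed transcription from mitosis to early G1. It returned across the genome within the 1 h release: 14360 of 14456 genes were at least 2-fold higher in early G1 than in mitosis, and 1 was at least 2-fold lower. These counts rest on the authors' scaling, and with equal medians they turn to 728 and 2500, with quantile normalization to 713 and 1195. The lower gene, named after its value was seen, was Ptcd1 (1.47 in mitosis, 0.618 in early G1). The median log2 ratio was 4.21, an 18.5-fold rise. Pou5f1 rose 29.0-fold to 113, Esrrb 26.9-fold to 84.2, Nanog 24.2-fold to 148, Sox2 22.0-fold to 299 and Klf4 17.9-fold to 193. The list of naive pluripotency factors lay 0.39 above the median gene (percentile 86.90), within the range of 99% of random lists.

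The G2 and mitosis genes, whose products drive chromosome segregation, regained least. All 35 were at least 2-fold higher than in mitosis, but their median lay 0.87 below that of the median gene (percentile 0), and 14 lay at least 2-fold below it. Top2a, which encodes topoisomerase II alpha, went from 2.37 to 6.48, Mki67, the gene of the proliferation antigen Ki-67, from 1.45 to 4.12, Cenpa, the centromeric histone gene, from 2.25 to 9.47, and Cdc25b from 0.341 to 1.53. The lists that had kept more signal in mitosis rose by less: immediate early genes lay at -0.62 (percentile 0), G1 cyclins and CDK inhibitors at -0.72 (percentile 0.07) and p53 targets at -0.33 (percentile 0.03). ATF4 and unfolded protein response genes lay at -0.29 (percentile 0.10), with Chac1 going from 0.264 to 3.17 and Asns from 2.70 to 94.5. With a pseudocount of 0.5 the p53 and ATF4 medians turned to 0.17 and 0.18 above the median gene. Over all settings the p53 list stayed at percentile 0.25 or less, while the ATF4 list reached 0.955, inside the range of 99% of random lists. Both ratios use the mitotic column, so a list high against asynchronous cells tends to be low here.

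The largest rises among genes above the median level were those of Saa3 (0.0543 to 40.9), Slc25a47 (0.151 to 42.0), Atat1 (0.437 to 87.6), Msmp (0.123 to 30.2), Trp53i11 (0.0765 to 23.7) and Tceal8 (0.555 to 87.1). The smallest changes were those of Slc5a2 (3.44 and 2.58), Gpr162 (1.57 and 1.83), Npff (4.35 and 6.54), Olfr543 (14.2 and 22.8), Paf1 (11.6 and 22.0) and Tubb4b (24.9 and 50.8). Msmp overlaps Rgp1 and Slc5a2 overlaps Rusf1 in the RefSeq annotation.

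Timing was read against the asynchronous level. Of the genes at least 2-fold lower in mitosis, 14274 also had a ratio to asynchronous cells in early and late G1, and 14192 of these (99.4%) were at least 2-fold above mitosis in early G1, 79 were so only in late G1, and 3 in neither (Serf1, Paf1 and Usp29, named after their values were seen). Shares of the asynchronous signal were taken here with the pseudocount added to both signals. By early G1, 12942 (90.7%) were above 50% of their asynchronous signal and 9081 (63.6%) were at or above all of it. Another 961 (6.73%) passed 50% only in late G1, and 371 (2.60%) in neither. With equal medians 902 genes were lower in mitosis, and the shares of 99.4%, 90.7% and 63.6% became 23.7%, 54.7% and 9.42%, and with quantile normalization 878 genes and 29.6%, 56.2% and 13.7%. Transcription passed the asynchronous level by at least 2-fold at 2596 genes in early G1 and 2483 in late G1, with 1079 in both (645 with equal medians and 546 with quantile normalization). Independent sets of these sizes would share 440.6 of the 14631 genes. Both ratios share the asynchronous column, so part of the excess may come from that column.

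Early G1 was also set directly against asynchronous cells. The p53 targets stood highest, with 17 of 25 at least 2-fold higher and a median 1.09 above the median gene (percentile 100). The 23 SRF and YAP targets and cytoskeleton genes lay 0.70 above (percentile 99.99), with 12 at least 2-fold higher; Tpm1, a tropomyosin gene, had 41.2 in early G1 and 15.7 in asynchronous cells, and Flna, the filamin A gene, 30.8 and 15.3. G2 and mitosis genes (-1.14), tubulins (-0.98), ATF4 and unfolded protein response genes (-0.73), ribosomal proteins (-0.69) and glycolysis (-0.64) stood below random lists, at percentiles of 0.06 or less. Over all genes, 2596 were at least 2-fold higher and 1397 at least 2-fold lower, a split that turns to 1320 and 2155 with equal medians.

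The third comparison asked what changed between early and late G1. The column medians were close (median log2 ratio -0.08), yet 2226 of 14699 genes were at least 2-fold higher in late G1 and 1106 at least 2-fold lower. Splicing, proteasome and RNA polymerase II genes had medians below the median gene by more than random lists did. Their median signal was 1.48- to 1.49-fold lower, and most of their members stayed within 2-fold. The 47 RNA splicing factors lay 0.49 below the median gene on the log2 scale (median -0.49, percentile 0.04), 2 of them at least 2-fold lower, with Tra2a going from 83.6 to 42.9 and Sf3b4 from 67.9 to 34.9. The 39 proteasome genes lay at -0.50 (percentile 0.25), 5 of them at least 2-fold lower, with Psmd8 going from 50.1 to 18.4 and Psmc5 from 69.8 to 30.7, while Psmb9, an immunoproteasome gene, went from 2.38 to 8.53. The 34 genes of the RNA polymerase II machinery lay at -0.49 (percentile 0.46), 8 of them at least 2-fold lower, with Polr2i going from 124 to 51.3 and Ccnt2, which encodes cyclin T2, from 32.1 to 12.9. The SRF and YAP targets and cytoskeleton genes, with a median 1.53-fold lower, lay at -0.53 (percentile 0.22), 4 of 23 at least 2-fold lower, with Flna going from 30.8 to 14.0 and Tpm1 from 41.2 to 19.7. In the least favourable setting the last 3 groups lay at percentiles 0.54, 0.64 and 0.74, inside the range of 99% of random lists.

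The fibroblast feeder markers moved the other way. Of the 30 fixed beforehand, 15 were in the table. These had a median 1.07 above the median gene (percentile 99.54), and 7 were at least 2-fold higher in late G1. Col1a1, a collagen gene (chromosome 11, TSS at 94936224), went from 1.97 to 9.37, Snai2 from 1.02 to 5.64, Loxl1 from 11.6 to 30.6 and Pdgfra from 2.48 to 6.42. In asynchronous cells Col1a1 had 5.44 and Snai2 0.727. The percentile of this list ran from 91.9 to 99.6 over the settings tried, and it was 99.1 when random lists were matched on gene span too. Matching on span, or leaving out genes under 2 kb, left 3 lists outside the range of 99% of random lists in place of 5. The number was 4 with a pseudocount of 0.5, no filter, a minimum mean of 2.5, genes at 0 kept or list means. It was also 4 with equal medians, which cannot change a value relative to the median gene. The number of 5 therefore depends in part on the random draw.

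Single genes changed further. Among those above the median level, Slc5a2 went from 2.58 to 60.8, Npff, a neuropeptide gene, from 6.54 to 102, Dlx4 from 2.97 to 33.2, Krt19, a keratin gene, from 3.29 to 34.8, Gpr132 from 3.45 to 35.7 and Mageh1 from 3.03 to 30.6. Creb3l3 fell from 50.4 to 3.00, Bex3 from 82.3 to 7.81, Smim26 from 29.9 to 2.81, Rfpl4 from 33.9 to 3.63, Tmem221 from 37.3 to 4.32 and Ebna1bp2 from 46.8 to 6.02. Of the 26 naive pluripotency factors, 1 was at least 2-fold higher and 4 at least 2-fold lower (percentile 58.36), with Gbx2 going from 26.0 to 5.19 and Tcl1 from 6.75 to 2.85. Sox2 had 299 and 317, Nanog 148 and 119, Klf4 193 and 183, Esrrb 84.2 and 93.5, and Pou5f1 113 and 80.0. With only genes of a mean signal of at least 2.5, the number of genes at least 2-fold higher in late G1 was 1255.

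**Figure D3:**
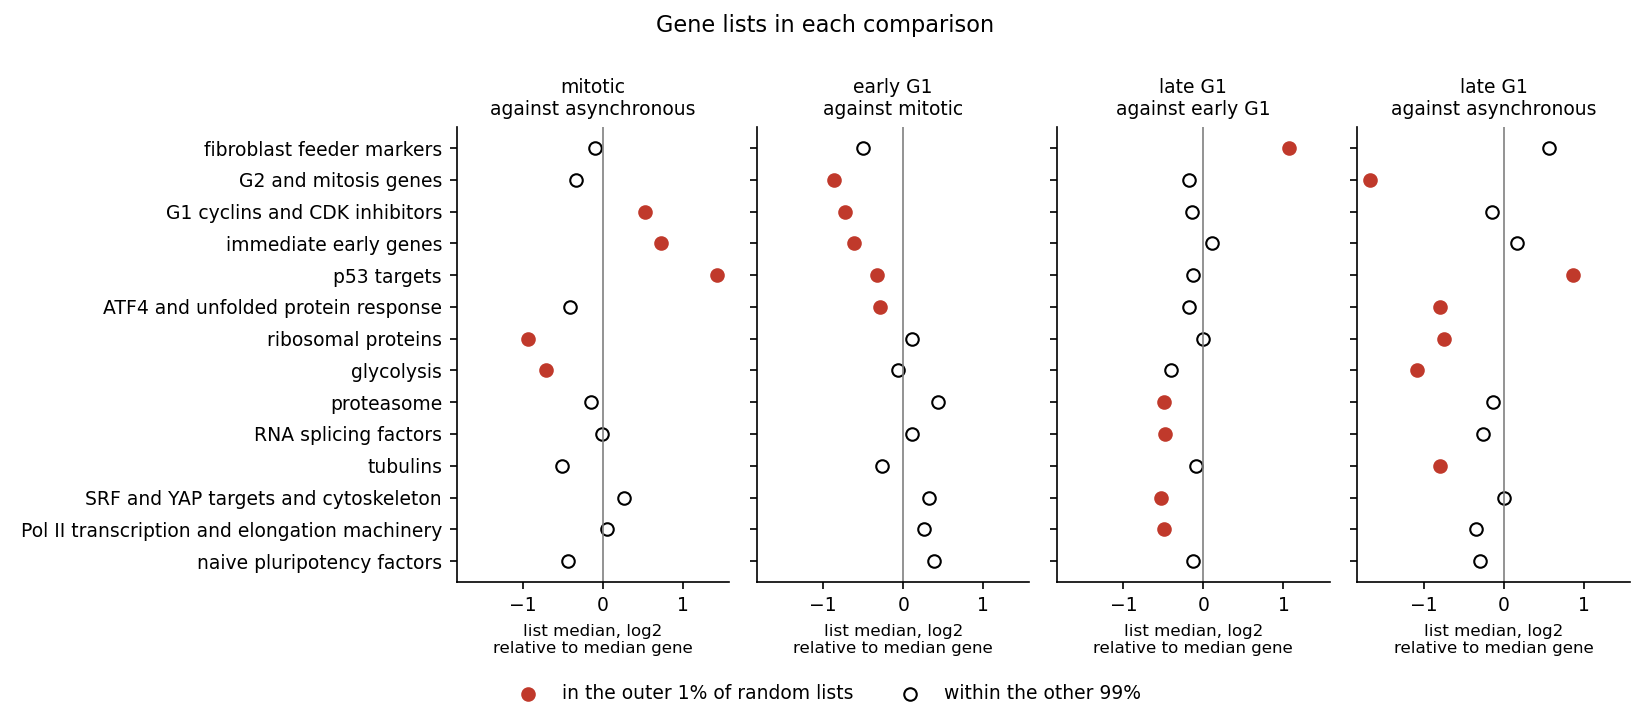
Each point is the median log2 ratio of a gene list relative to the median gene, for the lists outside the range of 99% of random lists in any of the 4 main comparisons and for the naive pluripotency factors. Filled points lie outside that range: p53 targets at 1.42 in mitotic against asynchronous cells and 0.86 in late G1 against asynchronous cells, and G2 and mitosis genes at -1.67 in the latter.

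The fourth comparison set late G1 against asynchronous cells. The G2 and mitosis genes were the lowest group: 23 of 35 were at least 2-fold lower and none at least 2-fold higher, with a median 2.76-fold below the asynchronous level (-1.67 relative to the median gene, percentile 0). Plk1, the mitotic kinase gene (chromosome 7, TSS at 122159507), had 5.38 in late G1 and 51.1 in asynchronous cells, Top2a 12.5 and 76.3, Cenpa 9.80 and 50.3, Kif23 4.50 and 22.5, and Ccnb1, which encodes cyclin B1, 17.2 and 67.4. The p53 targets were the highest group: 13 of 25 were at least 2-fold higher and none at least 2-fold lower, with a median of 2.10-fold (0.86 relative to the median gene, percentile 100). Mdm2, whose product targets p53 for degradation (chromosome 10, TSS at 117710078), had 288 in late G1 and 38.4 in asynchronous cells, Fas 11.7 and 0.695, Perp 43.3 and 6.31, and Pmaip1, which encodes NOXA, 67.5 and 11.8.

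Other groups stayed below the asynchronous level. The 20 glycolytic genes lay at -1.09 relative to the median gene (percentile 0), with 8 at least 2-fold lower; Slc2a3, a glucose transporter gene, had 36.1 in late G1 and 121 in asynchronous cells, Ldha 29.0 and 73.3, and Pgk1 6.44 and 19.1. The 13 tubulins lay at -0.79 (percentile 0.10), with Tubb5 at 108 and 382, Tuba1b at 128 and 353, Tuba1c at 37.0 and 136, and Tubb4b at 21.4 and 91.2. Their percentile was 0.865 when random lists were matched on span. Ribosomal proteins lay at -0.74 (percentile 0), with Rpl22l1 at 28.7 and 153 and Rps26 at 100.1 and 248. ATF4 and unfolded protein response genes lay at -0.79 (percentile 0.01), with Chac1 at 6.58 and 30.4, while Atf3 stood at 35.4 and 6.12. Ccnd1, a G1 cyclin gene, had 18.4 and 52.5, Ccne1 12.4 and 24.9, and Myc 23.4 and 17.5.

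Over all genes, 2483 of 14695 were at least 2-fold higher in late G1 and 755 at least 2-fold lower, and the median log2 ratio was 0.21. With equal medians the split was 1882 and 1174, and with quantile normalization 1532 and 1372. Among genes with a mean signal at or above the median, the highest ratios belonged to Mab21l1 (54.9 and 0.328), Oxld1 (651 and 26.6), Rgs14 (46.2 and 1.84), Npr1 (123 and 6.32), Cpz (57.1 and 3.21) and Ankrd65 (59.2 and 3.38). The lowest among these genes belonged to Nupr1 (1.52 and 45.8), Ccng2 (1.46 and 28.0), Mos (2.23 and 39.3), Gnb3 (36.1 and 379), Samd1 (26.7 and 258) and Plk1.

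The table also assigns each gene to 1 of 4 temporal classes. Early_Spike holds 4991 genes in the authors' deposited table, Early_Plateau 3910, Transient 3664 and Gradual 2296. Early_Spike genes had their highest value in early G1 in 94.3% of cases, Transient genes in late G1 in all but 1 case, and Gradual genes in asynchronous cells in 91.7%. Of the G2 and mitosis genes, 28 of 35 were Gradual and 0 were Early_Spike. Gradual, which holds 15.4% of all genes, also held 8 of 13 tubulins and 36 of 79 ribosomal protein genes. Another 37 ribosomal protein genes (46.8%) were Early_Plateau, against 40.5% in random lists matched on level (percentile 88.3). The proteasome genes were mostly Early_Spike (27 of 39, or 69.2%), against 41.0% in such random lists. G1/S and E2F target genes, which prepare DNA replication, were mostly Early_Plateau (20 of 36, or 55.6%), against 30.6%. How the classes were made is not given, but Early_Spike, Transient and Gradual follow the highest column closely. These counts are therefore not taken as independent of the comparisons.

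**Figure D4:**
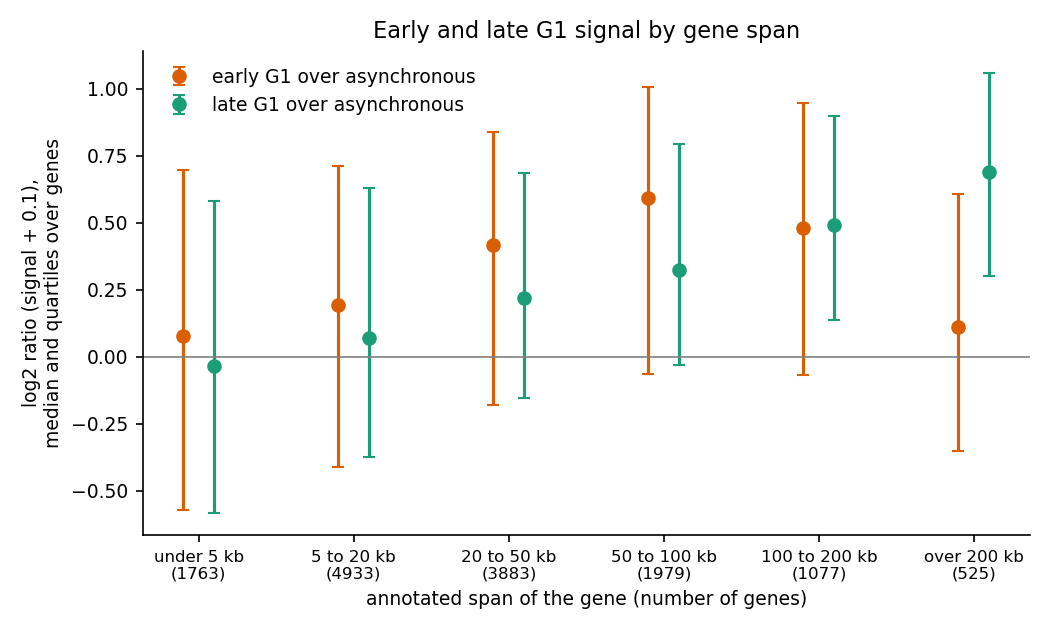
Points are the median, and bars the quartiles over genes, of the log2 ratio (signal plus 0.1) of early G1 and late G1 over asynchronous cells in 6 classes of annotated gene span, with the number of genes under each class. The early G1 median peaks at 0.59 for genes of 50 to 100 kb and is 0.11 above 200 kb, while the late G1 median climbs to 0.69.

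Gene span went with the timing. The median log2 ratio of early G1 over asynchronous cells was 0.08 for genes under 5 kb, 0.42 at 20 to 50 kb, 0.59 at 50 to 100 kb and 0.11 for the 525 genes over 200 kb. In late G1 the same classes had medians of -0.03, 0.22, 0.32 and 0.69. From early to late G1 the genes over 200 kb rose by a median log2 ratio of 0.60, while genes of 50 to 100 kb had a median of -0.17. The signal also fell with span: its asynchronous median was 22.1 under 5 kb, 9.12 at 20 to 50 kb and 3.02 over 200 kb. The late G1 column was higher at its low end (5th percentile 1.66, against 0.803 in early G1 and 0.858 in asynchronous cells). Low level was not separated from span in the late G1 medians. Spans come from the RefSeq annotation, which may not be the transcript model the authors counted over.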

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

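The 1.5-fold and 4-fold thresholds, the genes listed at 0 kept, the 2 kb span minimum, the span-matched lists and the list means were chosen after seeing the data. Of the values that answer a comparison, 183 alternatives stayed within 1.5 times or 0.2 (log2), 66 moved and 1 reversed; of the others, 780 stayed, 154 moved and 2 reversed. By construction, rescaling removes the general mitotic fall, other thresholds change counts, and a larger pseudocount shrinks the ratios of weak genes most. Keeping genes listed at 0 also adds their ratios to the counts by construction. The cause was otherwise not tested. No paired analysis was possible because the table holds 1 combined column per group; the limma, camera, fry, replicate-block and leave-one-out alternatives were not run for that reason.

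Mitotic against asynchronous, higher genes numbered 3, and 5 at pseudocount 0.02, 1690 with median centring, 1165 with quantile normalization, 31 with genes at 0 kept, 7 at 1.5-fold and 1 at 4-fold. Lower genes numbered 908 with centring and 885 with quantile normalization. The median log2 was -3.23 at pseudocount 0.5, -4.14 at 0.02 and -4.20 from column totals. Early G1 against mitotic, higher genes numbered 728 with centring and 713 with quantile normalization. Lower genes numbered 0 at pseudocount 0.5, 3 at 0.02, 2500 with centring, 1195 with quantile normalization, 27 with genes at 0 kept, 5 at 1.5-fold and 0 at 4-fold. The median log2 was 3.56, 4.44 and 4.42 from the same alternatives. The mean of each list in place of its median gave 8 lists apart. At pseudocount 0.5 the p53 targets reversed to 0.17 and the ATF4 genes to 0.18.

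Late against early G1, higher genes numbered 1255 at a minimum mean of 2.5, 3646 at 1.5-fold and 511 at 4-fold, and lower genes 3456 and 113 at those folds. The shift of -0.08 reversed to 0.066 with the mean over genes. Lists apart numbered 3 with the 2 kb minimum and 3 with span matching. Late G1 against asynchronous, higher genes numbered 1637 at a mean of 2.5, 1532 with quantile normalization, 4484 at 1.5-fold and 648 at 4-fold. Lower genes numbered 1174 with centring, 1372 with quantile normalization, 1804 at 1.5-fold and 118 at 4-fold. Early G1 against asynchronous, higher genes numbered 1320 with centring, 1245 with quantile normalization, 5337 at 1.5-fold and 377 at 4-fold. Lower genes numbered 925 at a mean of 2.5, 2155 with centring, 2526 at 1.5-fold and 309 at 4-fold.

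For the timing of genes lower in mitosis, centring and quantile normalization, which keep few such genes, gave 214 and 260 regained in early G1, 493 and 493 above 50% in early G1, 182 and 178 only in late G1, 227 and 207 in neither, and 85 and 120 at the asynchronous level. Genes above 50% only in late G1 numbered 619 at a mean of 2.5, 1500 at 1.5-fold and 234 at 4-fold, and those in neither 945 and 42 at those folds, where the fold also sets the share to be regained. Genes above asynchronous in both early and late G1 numbered 645 with centring, 546 with quantile normalization, 2512 at 1.5-fold and 173 at 4-fold. Depth is unknown, so how far it limits low values was not assessed.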

Other observations

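Apart from the histones in late G1 against mitosis, the groups described here stayed within the range of 99% of random lists. This holds for the main setting of the comparisons given for them. The replication-dependent histones lay outside that range in late G1 against mitosis, at percentile 0.115 (-0.53). In late G1 against asynchronous cells the formative and primed pluripotency genes lay at percentile 0.75 of random lists, with Pou3f1 at 9.07 and 19.1, just inside the range of 99% (0.13 in the most extreme setting). The G1/S and E2F target genes lay at percentile 1.30, although Mcm7, a replicative helicase gene, had 140 in late G1 and 56.3 in asynchronous cells and Ccne1 had 12.4 and 24.9. Cholesterol synthesis genes lay at percentile 97.96 from early to late G1. LIF-STAT3 targets lay at percentile 1.225 and Wnt-TCF targets at 7.545 in that comparison, with Gbx2 going from 26.0 to 5.19 and Axin2, a feedback inhibitor of Wnt signalling, from 51.2 to 9.66. Replication-dependent histone genes lay at percentile 1.495 there, with Hist3h2a going from 191 to 54.0, and cohesin, condensin and CTCF genes at 1.20. The medians of the LIF-STAT3 (-0.54), histone (-0.50) and cohesin (-0.50) lists were as far below the median gene as those of splicing or proteasome genes. In the most extreme settings the Wnt-TCF list reached percentile 0.17, the histones 0.10 and the cohesin list 0.485, outside that range.

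Heat shock genes lay at percentile 3.15 in late G1 against asynchronous cells, yet 5 of 20 were at least 2-fold higher, among them Hspa1a (6.05 and 0.944) and Dnaja4 (40.4 and 11.8). Apoptosis regulators lay at percentile 68.13, with 4 of 18 at least 2-fold higher. Apaf1 had 28.1 and 6.61, and Hrk 1.54 and 4.04. Oxidative phosphorylation (percentile 44.24), cohesin, condensin and CTCF (46.86), histone acetylation and bromodomain factors (50.76), and nuclear pore and lamina genes (55.65) lay in the middle of random lists in that comparison. In early G1 against asynchronous cells the cohesin list lay at percentile 95.47. In late G1 against asynchronous cells ribosome biogenesis lay at percentile 17.23, Polycomb, trithorax and DNA methylation genes at 7.98, lineage regulators at 3.63 and ERK pathway targets at 94.17.

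The tests of a uniform background, of polymerase travel and of scatter by G1 level given here were chosen after the result was seen; the other tests were written before it, but the use of an interval in the test of weakly transcribed long genes was added after its result was seen. No test had replicates, and intervals cover resampled genes only. Of the genes in the Transient class, highest in late G1, 77.1% gained more over asynchronous cells than the 5th percentile of the late G1 column (1.66), with an interval of 75.7% to 78.4%. A background equal for all genes in the authors' unit cannot exceed that value in more than 5% of genes. The share was 54.4%, 78.1% and 98.7% in 3 bins of rising asynchronous level. Nearly all genes of this class are highest in late G1, so some gain was set in advance. An equal fold is also a larger gain at a higher level. Only the size of the gain bears on a background, with medians of 1.84, 3.33 and 12.5 in these bins. Gains above 1.66 argue against such an equal background as the whole cause for the genes that have them. With the median of 1.84 in the lowest bin, it may carry part of the pattern among weak genes. A background that differs between genes, for example with span, was not tested. Feeder fibroblasts in the late G1 libraries may add to the pattern: their 15 markers had a median log2 ratio 0.79 above that of 24 lineage regulators, but the interval ran from -0.51 to 1.20 and this stays open. The other markers of the 30 fixed beforehand, Col1a2, Col3a1 and Dcn among them, had no values, and the reason is not known. The test covers only those with values. The mitotic shake-off may leave attached feeders out of the released groups, which would run against this explanation. Whether feeders stayed in the asynchronous group was not checked, so this step does not decide. Col1a1, an abundant fibroblast gene, reached 9.37 in late G1 and 5.44 in asynchronous cells, and the release itself, which separates these groups, remains an untested biological explanation.

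Genes over 200 kb were lower than genes of 20 to 50 kb in early G1 against asynchronous cells by a median log2 difference of -0.31 (interval -0.38 to -0.23), and higher by 0.47 in late G1. The gap in late G1 was not split by level. A candidate explanation is that polymerases had not yet crossed long genes 1 h after release, for which a gap of at least 1 was required and was not reached. The low level of long genes could also contribute: within the 3 bins of the asynchronous level, each of 25% of genes, that held at least 20 such genes, the gaps were -0.18, -0.27 and -0.17. All 3 kept over 50% of the whole gap, which met the bound written against this explanation, but the smallest had an interval of -0.36 to -0.04, so neither explanation is decided.

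For the genes that kept more signal in mitosis, a carry-over of asynchronous cells alone would leave 1 share for every gene. Among genes above the median asynchronous level the 95th percentile of the mitotic share was 4.66 times the 5th (10.7% against 2.30%). This passed the bound written against that explanation. The spread restates that genes differ, however, and scatter of small mitotic values at unknown depth could widen it. It therefore does not decide whether carry-over together with scatter was the cause. Carry-over of G2 cells was predicted to put the G2 and mitosis genes at least 1 above the median gene on the log2 scale. They lay at -0.34 relative to it (interval -0.53 to -0.13). Part of this value comes from the pseudocount of 0.1, which weakens the fall of weak genes. With a pseudocount of 0.02 the log2 ratio of the median gene moved from -3.89 to -4.14. The value is therefore read as no excess, which argues against this explanation, and not as a deficit. Of the 100 genes that kept most, 91 were in the lowest 25% of the asynchronous level, but that level is the denominator of the share, so this does not decide whether scatter of weak genes plays a part. With the level read from early and late G1, the log2 spread of the share in the highest 25% of genes was 0.68 of that in the lowest 25% (interval 0.64 to 0.73), between the bounds set for and against scatter, and it stays open. All 25 p53 targets had a median 1.42 above the median gene, with a wide interval of 0.38 to 1.98. The 15 of them in the top 25% of the asynchronous level had a median 1.55 above it (interval 1.18 to 2.04). The nocodazole treatment of the mitotic and released groups stays open as untested, since no mitotic cells without it were analysed here.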
